A study of Mus musculus with 17 samples.

How the data were processed

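The deposited values were raw counts of reads per Ensembl gene, which per the authors' notes came from stranded polyA-selected libraries on a HiSeq2500, aligned to GRCm38 with HISAT2 2.0.4 and counted with HTSeq 0.6.1. The authors also named DESeq2 1.10.1. The strand setting and the annotation release of the counting were not stated. Every one of the 17 libraries listed 47729 genes and 5 summary entries that name no gene, which were left out. Of the genes, 47310 (99.12%) matched GENCODE M21 by Ensembl ID, and the 419 others held 0.0228% of the counts. No pair of libraries was identical. Reads assigned to no gene, as multiply aligned, unaligned, ambiguous or without a feature, were 47.7 to 51.9%. Most of these were multiply aligned (36.2 to 45.2% of all), while 2.28 to 7.82% had no feature.

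The 8 libraries of the set with both lines (4 groups, n = 2, 1 per line) were fitted together with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with groups, 15525 in all, and scaled by TMM (factors 0.964 to 1.033). The quasi-likelihood fit used group means, no block and no robust option, with 4 residual degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment over all tested genes in each comparison, and a gene was called at an adjusted p under 0.05. The fit assumes independent libraries and a dispersion trend shared across genes. With the line as a block there were 3 residual degrees of freedom, and the common coefficient of variation went from 0.225 to 0.176. Residuals of lines were correlated between groups at 0.04 to 0.40, so a line effect exists, and R1 and CGR8 also differ in passage. How the lines differ in their response to a medium cannot be tested with 1 library per line and medium. Genes highest or lowest in LIM were tested by the larger of both p in LIM against L2i and LIM against LFAI at 4 days, with both folds in 1 direction (intersection-union test).

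The 23 gene lists were tested by camera in limma 3.58.1 on log2 CPM with a prior count of 2, at a preset correlation of 0.01, for lists with 3 or more tested members, adjusted over lists within a comparison. The test treats the members as nearly independent, and with the correlation estimated from the data no list passed in any comparison. Counts of list members that rose or fell use the adjustment over all genes, and counts over the list alone adjust the members only. List medians with bounds replace folds of genes with 0 counts in the lower group by the bound described below. Lists hold from 6 to 20 tested members, so a share of a small list moves in large steps. Some genes are in more than 1 list, so results of such lists are not independent. Among them, Tfcp2l1 is in the naive and STAT3 lists, Etv4 in the early epiblast and MEK/ERK lists, and Smad7 in the Nodal and BMP lists. Dnmt3b is in the early epiblast and DNA methylation lists, and Col4a1 and Lamb1 are in the basement membrane and primitive endoderm lists.

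Named genes followed a fixed rule. A panel of 20 genes was set in advance, of which the text gives those past the threshold and may give the others as values. To these come the 6 largest rises and 6 largest falls of each of the first 4 comparisons and the 3 largest each way of the last 2. These had to be called, to move in the same direction in both lines, to reach 5 CPM in the higher group, and to have a name that is not predicted, a clone or a pseudogene. Up to 4 members of each list with the smallest p may be named. For LIM as highest or lowest, 6 genes each way were taken by the smaller of both folds. In the time course, 5 genes each way were taken that moved in 1 direction on every day step with a mean of 10 CPM or more, where a step from 0 to 0 counts was no move. Folds with 0 counts in the lower group are given as at least the fold over a floor of 3 counts, taken over the summed depth of both libraries of the lower group, or over the single day 0 library in the time course, and folds on 1 to 3 counts as a ratio with a 95% counting interval. Panel levels are means of CPM with SD over both lines.

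The 9 time course libraries were scaled together by TMM and given as log2 CPM with a prior count of 2, after a filter of 1 CPM (15682 genes). They were kept apart because the coating and the sequencing protocol differ from those of the other set and because each point has 1 library. List medians were placed among 10000 random lists of the same size from 20 expression bins, and 1000 Poisson draws gave 95% intervals of counting error. Correlations with the other set used 14905 shared genes.

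Alternatives were set before the data were examined. They were DESeq2 size factors, no filter on low counts, the Wald test of DESeq2 1.42.0, limma-voom, the line as a block, only the 4 libraries of a comparison, a log2 fold threshold of 1, and each library left out in turn. For LFAI at 4 days against L2i, the time course libraries of day 0 and day 4 were also added with a term for the experiment. For lists they were fry, the estimated correlation, the block and left-out libraries. For the time course they were prior counts of 0.5 and 5, no filter, and only genes over 10 CPM. A further pair was chosen after seeing the data, leaving out the R1 L2i and R1 35 h libraries together, and leaving out the genes of chromosome 8. A group left with 1 library was assumed to vary like the others.

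The code was tried on simulated counts with known changes. In a comparison with 200 changed genes, 50 per fold size, it recovered 10% at 1.5-fold, 48% at 2-fold, 90% at 4-fold and 96% at 8-fold, with 7 false calls among 15049 tested genes and 0 calls in a comparison without change. The intersection-union test gave 1 false call. Of 200 unchanged lists of 15 genes, 1% lay over the 97.5th percentile of 500 random lists and 5% below the 2.5th, and all lists changed 1.5-fold or 2-fold were found above. Both libraries of this trial were Poisson counts at day 0 levels, and no gene outside the list changed. In the time course many other genes change too, so these rates do not carry over to it.

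No test was made of reads, splicing or strand, since the values are counts per gene. Proteins, methylation and cell morphology were not measured here, so statements are limited to RNA. No accounts of other studies were used. Results that need items withheld for evaluation were left out.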

Results

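Polyadenylated RNA of mouse embryonic stem cells was sequenced and counted per gene, with LIF present in every medium. The question was how expression differs between a naive state, a state held under MEK inhibition without Wnt ligands, and cells moving toward a primed state. The first medium, L2i, contained the MEK inhibitor PD325901 and the Wnt pathway activator CHIR99021. The next, LIM, contained PD325901 with IWP2, which blocks secretion of Wnt ligands. LFAI contained FGF2, Activin A and IWP2, and was sampled after 35 h and after 4 days. Each of these 4 groups had 1 library of line R1 and 1 of line CGR8 (n = 2). Cells of the LIM libraries in this set had been in LIM for 4 (R1) and 6 (CGR8) passages. LFAI against LIM therefore differs in both medium and time since L2i. Passages in 2i (PD325901 with CHIR99021) were 10 (R1) and 8 (CGR8) for L2i, and 5 and 5 for LIM. They were 9 and 7 for LFAI at 35 h, and 3 and 9 at 4 days. Time in 2i thus also differs between the groups compared, and its effect cannot be told apart from that of the medium. A separate time course of R1 cells had 9 single libraries (n = 1 each), day 0 in L2i and days 1 to 4 in LIM or LFAI, on another coating and with another sequencing protocol, so its values were not tested.

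In the set with both lines, the R1 and CGR8 libraries held 22.6 M and 15.1 M gene counts in L2i, 15.8 and 16.3 in LIM, 15.9 and 15.4 after 35 h in LFAI, and 15.5 and 15.3 after 4 days. In the time course, day 0 held 13.5 M, LIM days 1 to 4 held 12.9, 13.6, 13.5 and 13.5, and LFAI days 1 to 4 held 13.7, 13.1, 13.3 and 13.3. Between 18733 and 22303 genes were detected per library, the fewest in R1 L2i, the deepest library. Expression of the 15525 tested genes correlated between lines at 0.974 to 0.983 within groups, although genes are not independent replicates. The panel of 20 fixed genes in the 8 libraries shows Zfp42 at a similar level in 3 groups and low after 4 days in LFAI, and Nanog lower in LIM and at 35 h than in L2i and lowest after 4 days.

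**Figure D1:**
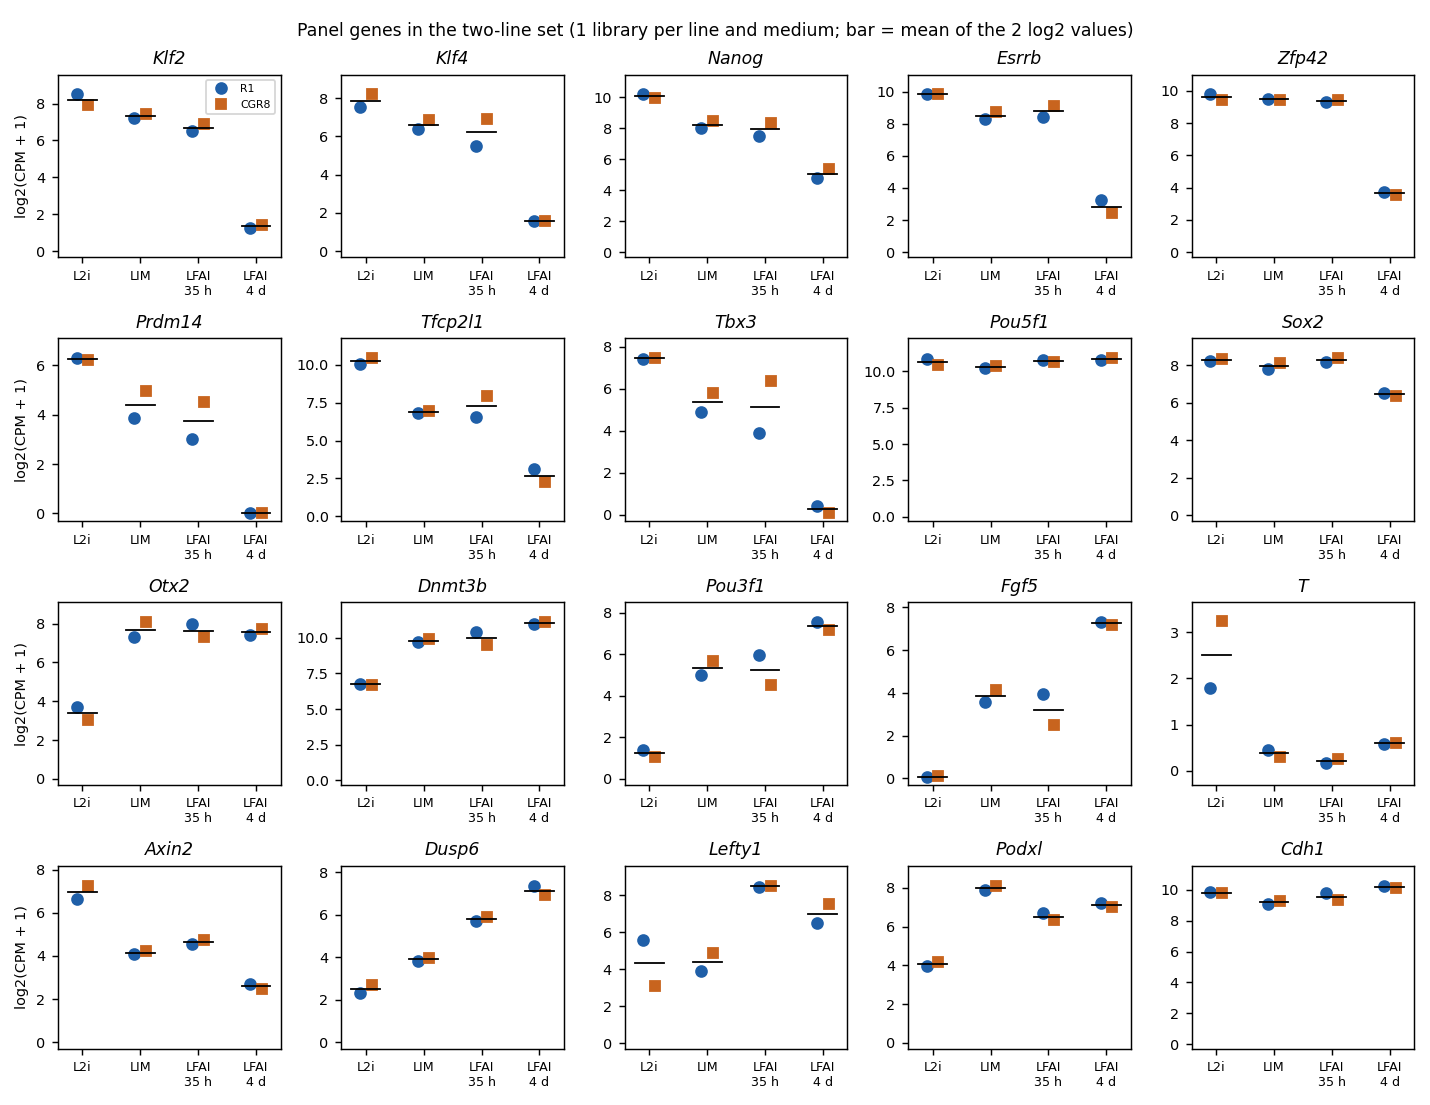
Expression of the 20 panel genes in the 8 libraries of the set with both lines, as log2 of CPM plus 1. Circles are R1, squares are CGR8, and bars are the mean of both values.

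Genes were tested with the edgeR quasi-likelihood test and Benjamini-Hochberg adjustment (two-sided), and a gene was called at an adjusted p under 0.05. Errors are SE of the log2 fold or SD of CPM (n = 2 per group). The SE is the size of the fold over the square root of the F statistic of its test. That statistic pools the spread over genes and groups, so the SE can be smaller than the spread between the lines. Bounds of the form "at least" and counting intervals cover counting error only. The groups, comparisons, gene panel and 23 gene lists were set before the data were examined. Every called gene moved in the same direction in both lines in each of the 6 comparisons. This adds little evidence of agreement, as the lines were the only replicates and opposite moves widen the spread in the test. List tests compared the list with all other tested genes at a preset correlation between genes of 0.01, and were adjusted over the 23 lists.

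The first comparison, LIM against L2i, asked which genes change when cells under MEK inhibition lose Wnt activation. Genes of the epiblast after implantation were on in LIM, while naive factors fell in part and Wnt target genes fell far. Otx2, a homeobox factor that marks the epiblast after implantation, rose 21.8-fold, from 9.70 ± 3.38 to 213 ± 81.3 CPM (adjusted p = 0.00025). Dnmt3b, a DNA methyltransferase of that stage, rose 8.35-fold to 885 ± 108 CPM (adjusted p = 0.00032), and Pou3f1 rose 29.9-fold (log2 4.90 ± 0.56, adjusted p = 0.0009). Fgf5, counted 2 times in L2i, rose by a ratio of 251.5 (counting interval 69.2 to 2083, adjusted p = 0.00069). Of 17 early epiblast genes, 15 rose, among them Sox4 (15.1-fold) and Sall2 (log2 3.00 ± 0.31), Etv4 fell 8.1-fold, and Foxd3 was not called. The list had a median log2 fold of 2.58 and passed its test (adjusted p = 4.8e-07, adjusted p = 0.36 with an estimated correlation). The counts were the same adjusted over the list alone.

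Among 18 naive pluripotency factors, 10 fell and none rose (12 and 0 adjusted over the list alone). Tfcp2l1, a naive factor downstream of LIF, fell 10.7-fold to 116 ± 8.48 CPM (log2 -3.42 ± 0.45, adjusted p = 0.0016), and Nanog fell 3.48-fold to 307 ± 76.6 CPM (adjusted p = 0.0049). Nr5a2 fell 2.51-fold (log2 -1.33 ± 0.23). Klf2 fell 1.87-fold (adjusted p = 0.019), Esrrb fell 2.49-fold (adjusted p = 0.015) and Prdm14 fell 3.48-fold (adjusted p = 0.046). Zfp42 (log2 -0.16 ± 0.15, adjusted p = 0.49), Pou5f1 (-0.34 ± 0.16, adjusted p = 0.17) and Sox2 (-0.31 ± 0.15, adjusted p = 0.17) were not called. Klf4 (log2 -1.27 ± 0.41, adjusted p = 0.064) and Tbx3 (-2.05 ± 0.66, adjusted p = 0.062) were not called either, and both were called with the line as a block (log2 -1.24 and -2.22). The naive list had a median of -1.28 and passed its test (adjusted p = 4.2e-05, adjusted p = 0.36 with an estimated correlation). Klf2 was not called without the R1 L2i (log2 -0.57), R1 LIM (-0.79) or CGR8 LIM library (-1.01), nor Esrrb without the R1 L2i (-1.31), CGR8 L2i (-1.31) or R1 LIM library (-1.11). Prdm14 was not called without the R1 L2i (log2 -1.76), CGR8 L2i (-1.83), R1 LIM (-1.34), R1 4-day (-1.80) or CGR8 4-day LFAI library (-1.79). Without either 35 h library, Klf4 (log2 -1.27) and Tbx3 (-2.05) were called.

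Of 14 Wnt/beta-catenin targets, 9 fell and only Lef1 rose (11 and 2 adjusted over the list alone). Axin2, a feedback inhibitor of the pathway, fell 7.43-fold, from 125 ± 36.4 to 16.8 ± 1.46 CPM (adjusted p = 0.00021). Sp5 fell 61.9-fold (log2 -5.95 ± 0.81), Notum fell 2.29-fold (log2 -1.19 ± 0.16), and Cdx1 was lower by a ratio of 575.2 (counting interval 196.5 to 2792). T, the brachyury gene of the primitive streak and also a Wnt target, fell 17.3-fold (log2 -4.11 ± 0.74, adjusted p = 0.0063). The list had a median of -1.66 (adjusted p = 4.2e-05, adjusted p = 0.32 with an estimated correlation).

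Cholesterol synthesis genes rose as a group, 11 of 15 with none falling (13 and 0 adjusted over the list alone). Lss, the lanosterol synthase, rose 2.98-fold (log2 1.57 ± 0.12, adjusted p = 0.00021), and Hmgcs1 and Pmvk rose 1.99-fold and 2.67-fold. The list median was 0.67 (adjusted p = 4.2e-05, adjusted p = 0.36 with an estimated correlation). Of 10 primitive endoderm markers, 3 rose and none fell (7 and 0 adjusted over the list alone), with a median of 1.89 (adjusted p = 0.00053, adjusted p = 0.32 with an estimated correlation). Col4a1, a basement membrane collagen, was the strongest of them, up 14.2-fold from 8.73 ± 2.21 to 125 ± 2.65 CPM (adjusted p = 0.00021). The others that rose were Lamb1 and Dab2. Col4a1 and Lamb1 also belong to the basement membrane list, which did not pass.

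Genes of surface, methylation and signalling moved inside lists that did not pass. Podxl, an apical sialomucin of epithelial lumens, rose 15.9-fold, from 15.9 ± 1.52 to 253 ± 28.5 CPM (adjusted p = 2.9e-05). Cdh1, the epithelial cadherin, fell 1.53-fold (log2 -0.62 ± 0.17, adjusted p = 0.034), a call lost without the R1 L2i (log2 -0.57), CGR8 L2i (-0.66), R1 LIM (-0.51) or CGR8 LIM library (-0.73). Of 20 apical polarity, junction and lumen genes, 6 rose and 4 fell (adjusted p = 0.51), Cgn (9.84-fold) and Cldn6 (5.14-fold) among the risen. Dnmt3l rose 19.7-fold to 616 ± 19.7 CPM and Tet2 fell 3.03-fold, with 4 risen and 1 fallen of 8 genes of DNA methylation machinery (adjusted p = 0.054). Dusp6, a phosphatase induced by ERK, rose 2.96-fold but stayed low, at 14.0 ± 0.784 CPM (adjusted p = 0.0021). Of 16 MEK/ERK target and feedback genes 4 rose and 1 fell (6 and 2 adjusted over the list alone, adjusted p = 0.052, 0.023 with the line as a block). Lefty1, a Nodal inhibitor, was not called (log2 -0.38 ± 0.69, adjusted p = 0.74). It was lower in LIM in R1 (log2 -1.74) but higher in CGR8 (1.91), so the pooled value does not show a lack of change.

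The 18 lists that did not pass had adjusted p between 0.052 and 0.96. Of 10 core pluripotency factors 3 rose, Lin28a 6.44-fold among them, and 1 fell (adjusted p = 0.36), and of 10 LIF/STAT3 targets Pim1 (3.07-fold) and Tfcp2l1 fell (adjusted p = 0.068), Pim1 not without R1 L2i (log2 -1.50) or R1 LIM (-1.26). Of 6 neural progenitor genes 4 rose, Pax6 9.25-fold and Nes 3.11-fold among them, and Olig3 fell (adjusted p = 0.16). Basement membrane and integrin genes (4 rose, 2 fell of 16, adjusted p = 0.23), Nodal/Activin targets (2 and 2 of 9, adjusted p = 0.68) and BMP targets (2 and 1 of 8, adjusted p = 0.32, Id1 up 6.88-fold) did not move together. Of 15 glycolysis genes 2 rose, Slc16a3 20.5-fold, and none fell (adjusted p = 0.27), and of 15 genes of mitochondrial respiration 2 fell (adjusted p = 0.054). Among 10 p53 targets Bbc3 rose and Cdkn1a and Sesn1 fell (adjusted p = 0.71), and among 10 genes of the integrated stress response 2 rose and Asns fell 2.88-fold (adjusted p = 0.38). Of 13 germline genes silenced by DNA methylation 2 rose and 3 fell (adjusted p = 0.81), and none of 9 2-cell-like genes was called (adjusted p = 0.068, 0.023 with the line as a block, which called Tcstv3 at 0.046). Of 8 primitive streak, mesoderm and endoderm genes 1 rose and 1 fell (adjusted p = 0.96). Markers of other cells were mixed, with Krt18 up 21.6-fold and Cdx2 down by a ratio of 101.6 (counting interval 27.79 to 843.6) among 10 trophoblast markers (5 rose, 2 fell, adjusted p = 0.27). Of 7 fibroblast markers 3 rose, Fbn1 5.7-fold (adjusted p = 0.072, median 2.51, or 1.68 with bounds). Adjusted over the list alone, higher and lower counts became 5 and 1 for core factors, 3 and 3 for streak genes and for Nodal targets, 0 and 4 for STAT3 targets, and 4 and 4 for germline genes. They became 3 and 1 for BMP targets and for the stress response, 4 and 0 for fibroblast markers, and 0 and 1 for respiration. The median, mean and test direction differed in sign for streak genes (0.61, 0.02, down), germline genes (0.35, -0.03, down) and p53 targets (0.06, -0.02, down).

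Left-out libraries brought further lists past the threshold. MEK/ERK genes passed without R1 4-day (0.034), CGR8 4-day (0.036) or either 35 h library (0.044), and fibroblast markers without R1 4-day (0.046), CGR8 4-day (0.048) or either 35 h library (0.044). Methylation genes passed without R1 35 h (0.044) or CGR8 35 h (0.045), STAT3 targets without R1 L2i (0.04), either 35 h library (0.044) or R1 LIM (0.012), and glycolysis genes without R1 LIM (4.2e-05). Neural genes passed without CGR8 4-day (0.049), R1 35 h (0.048), CGR8 35 h (0.049) or CGR8 LIM (0.012), and 2-cell-like genes without R1 L2i (0.002), R1 35 h (0.01) or CGR8 35 h (0.0098). Respiration genes passed without CGR8 L2i (0.0099), R1 4-day (0.046), CGR8 4-day (0.048), R1 35 h (0.044) or CGR8 35 h (0.045).

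In all, 1750 genes were higher and 1212 lower in LIM than in L2i, 19.1% of those tested. The largest rises were in Car4 (at least 359.6-fold), Cacna1g (at least 142.6-fold), Enpp2 (at least 110.8-fold), Fignl2 (ratio 1154, counting interval 206.7 to 45620), Cldn2 (at least 70.35-fold) and Acta1 (at least 69.6-fold). The largest falls besides Cdx1 and Cdx2 were in Nkx1-2 (216-fold), Cnga4 (ratio 144.3, counting interval 49.09 to 702.2), Trpm1 (115-fold) and Htr5a (ratio 94.43, counting interval 25.82 to 784.8). The higher count fell to 934 without the R1 L2i library and to 1108 without R1 LIM. The lower count fell to 553 and 729 without the R1 or CGR8 L2i library and to 505 and 773 without the R1 or CGR8 LIM library. With 5 lists called, 12 were called without either 35 h library, and 8 and 9 without the R1 or CGR8 4-day library.

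**Figure D2:**
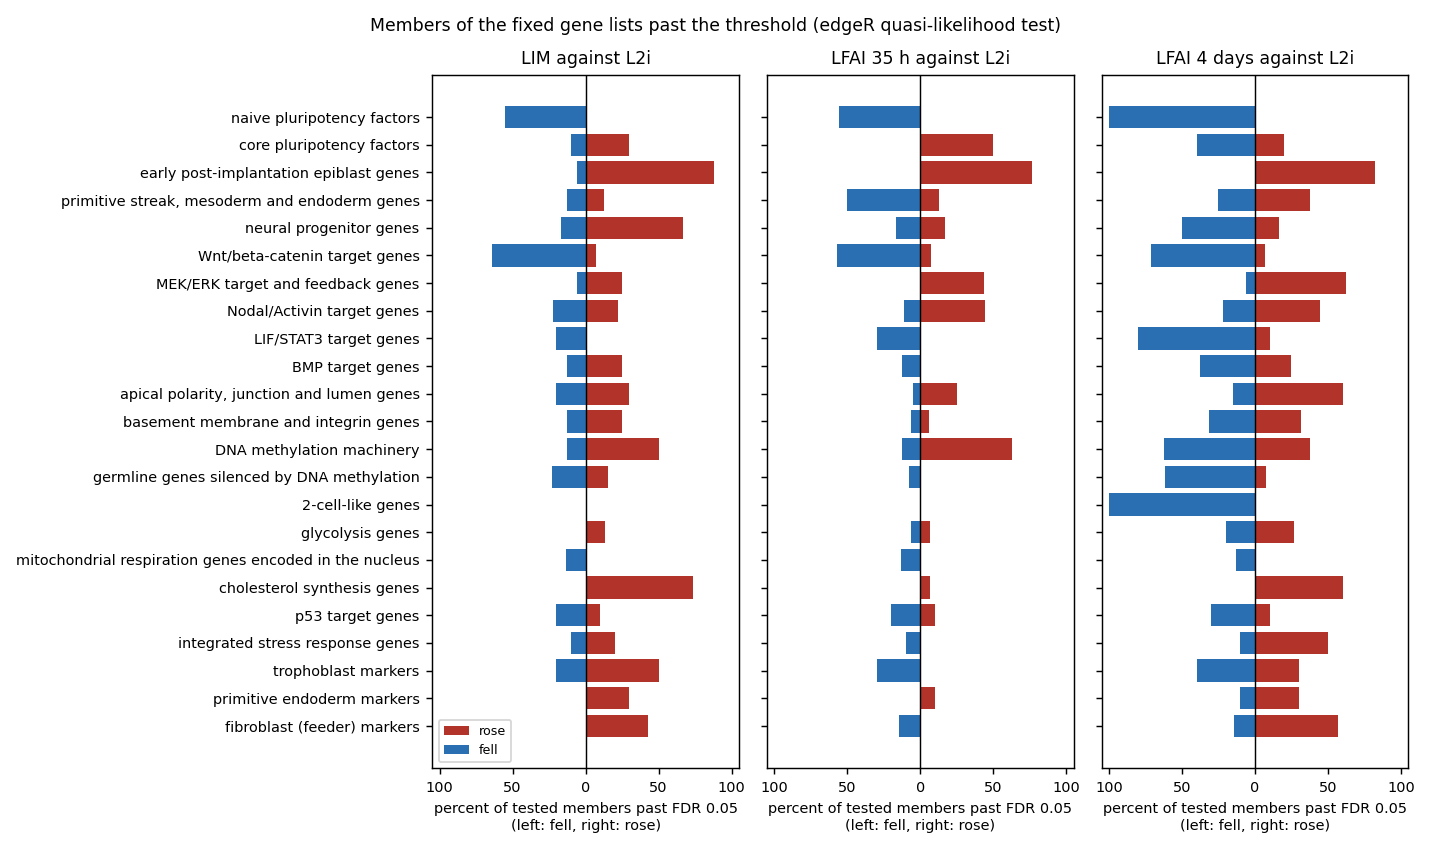
Percent of members of each fixed list that rose or fell in the 3 comparisons with L2i.

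The next comparison, LFAI at 35 h against L2i, asked what the first 35 h with FGF2 and Activin A and without MEK inhibition change. Of 16 MEK/ERK targets 7 rose, of 17 early epiblast genes 13 rose, and 8 of 18 naive factors were not called. Dusp6 rose 11.7-fold, from 4.74 ± 0.99 to 54.9 ± 4.52 CPM (adjusted p = 0.00017), and Spry4, a feedback inhibitor of FGF signalling, rose by a log2 fold of 4.95 ± 0.45 (adjusted p = 0.00042). Lefty1, a Nodal target, rose 13.1-fold to 357 ± 6.58 CPM (adjusted p = 0.012). Otx2 rose 20.8-fold to 204 ± 64.9 CPM (adjusted p = 0.00035), Dnmt3b rose 9.93-fold (adjusted p = 0.00033) and Pou3f1 rose 30.7-fold (adjusted p = 0.0011). Fgf5 was higher by a ratio of 175.5 (counting interval 48.16 to 1456), and Podxl rose 5.72-fold to 90.9 ± 16.9 CPM (adjusted p = 0.00021).

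Naive factors fell in the same count as in LIM, 10 of 18 with none risen (11 and 1 adjusted over the list alone), at a median of -1.03. Tfcp2l1 fell 7.23-fold (log2 -2.85 ± 0.44, adjusted p = 0.0038), Nanog fell 4.24-fold to 252 ± 102 CPM (adjusted p = 0.0034) and Klf2 fell 2.89-fold (log2 -1.53 ± 0.21, adjusted p = 0.0026). Klf4 (2.88-fold, adjusted p = 0.041), Esrrb (2.03-fold, adjusted p = 0.046) and Prdm14 (5.29-fold, adjusted p = 0.022) also fell. Zfp42 (log2 -0.26, adjusted p = 0.28), Pou5f1 (0.10, adjusted p = 0.75), Sox2 (-0.01, adjusted p = 0.99), Cdh1 (-0.24, adjusted p = 0.38) and Tbx3 (-1.84, adjusted p = 0.099, called with the line as a block at -2.24) were not called. Klf4 was not called without R1 L2i (log2 -1.82), CGR8 L2i (-1.11), R1 35 h (-0.98), R1 LIM (-1.51), CGR8 LIM (-1.52), R1 4-day (-1.52) or CGR8 4-day (-1.51). Esrrb was not called without R1 L2i (log2 -1.01), CGR8 L2i (-0.99), R1 35 h (-0.70), R1 LIM (-1) or CGR8 LIM (-1.02), nor Prdm14 without R1 L2i (-2.36), CGR8 L2i (-2.41) or R1 35 h (-1.80). Without the CGR8 35 h library Tbx3 was called (log2 -3.66).

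Early epiblast genes passed their list test with 13 of 17 risen and none fallen (14 and 0 adjusted over the list alone, median 2.73, adjusted p = 3.4e-09, adjusted p = 0.25 with an estimated correlation). The naive list passed at an adjusted p of 0.00079 (adjusted p = 0.54 with an estimated correlation). Wnt targets fell in 8 of 14 with Lef1 risen (9 and 1 adjusted over the list alone, median -2.32), and the list passed (adjusted p = 4.5e-05, adjusted p = 0.25 with an estimated correlation). Axin2 fell 5.21-fold (log2 -2.38 ± 0.22, adjusted p = 0.00048), Tnfrsf19 fell 13.4-fold and T fell 31.8-fold (log2 -4.99 ± 0.80, adjusted p = 0.0048). Of 16 MEK/ERK genes 7 rose and none fell, also over the list alone (median 1.06, adjusted p = 1.3e-05, adjusted p = 0.25 with an estimated correlation), Etv1 (5.3-fold) and Spry1 (4.93-fold) among them. Of 10 core factors 5 rose and none fell, including Lin28a (4.3-fold), Utf1 (4.04-fold) and Dppa4 (2.67-fold), and 6 rose over the list alone (median 0.70, adjusted p = 0.0015, adjusted p = 0.25 with an estimated correlation). Of 8 methylation genes 5 rose, Dnmt3l 17.1-fold and Dnmt3a 6.2-fold, and Tet2 fell, with the same counts over the list alone (median 1.09, adjusted p = 0.0074, adjusted p = 0.25 with an estimated correlation).

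The other 17 lists had adjusted p between 0.059 and 0.91. Nodal targets came nearest, with 4 of 9 risen and Gsc fallen (6 and 2 adjusted over the list alone), and passed without R1 L2i (0.018), R1 LIM (0.011) or CGR8 LIM (0.01). The 2-cell-like list passed without R1 35 h (0.01) and the stress response without R1 L2i (0.045) or CGR8 35 h (0.018). Of trophoblast markers, Tfap2c (9.82-fold, log2 -3.30 ± 0.35) and Cdx2 (at least 63.44-fold) fell and none rose (Krt18 was called higher with the line as a block, 0.0022), at a list median of -0.09, or -0.25 with bounds. Median, mean and test direction differed in sign for neural genes (0.10, -0.90, down), BMP targets (0.08, -0.79, down), p53 targets (0.04, -0.14, down), endoderm markers (-0.62, 0.10, down) and fibroblast markers (-0.72, 0.50, down). In all, 1141 genes were higher and 1111 lower. The largest rises were in Enpp2 (at least 141.8-fold), Tmem154 (at least 90.65-fold), Ccdc194 (at least 75.48-fold, not called without R1 L2i, log2 9.61), Bcl11a (ratio 971.6, counting interval 173.9 to 38420), Fgf15 (247-fold) and Myrf (213-fold). The largest falls were in Sp5 (ratio 1083, counting interval 194 to 42790), Cdx1 (ratio 538.9, counting interval 184.1 to 2616), Cnga4 (at least 135.2-fold), Csf3r (at least 83.19-fold), Cdx2, and Htr5a (at least 58.99-fold). Without R1 L2i or R1 35 h, 507 genes were higher in each case, and 453 and 369 were lower. Without CGR8 L2i or CGR8 35 h, 697 and 717 were lower.

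LFAI at 4 days against L2i asked how far 4 days carry the cells from the naive state. All 18 naive factors fell, and early epiblast genes stayed on. Pou5f1 went from 1820 to 1810 CPM in R1 and from 1380 to 1930 in CGR8. Zfp42, a zinc finger marker of naive cells, fell 68.3-fold, from 790 ± 134 to 11.6 ± 1.37 CPM (log2 -6.09 ± 0.19, adjusted p = 9.5e-07). Klf2 fell by a log2 fold of -7.57 ± 0.30, from 300 ± 87.7 to 1.57 ± 0.178 CPM (adjusted p = 2.4e-06), and Nanog fell 31.9-fold to 33.6 ± 9.28 CPM (adjusted p = 2e-05). Pou5f1, shared by naive and primed cells, was not called (log2 0.22 ± 0.16, adjusted p = 0.28), while Sox2 fell 3.59-fold (log2 -1.84 ± 0.15, adjusted p = 3.8e-05).

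The remaining panel genes of the naive state fell further than in the earlier comparisons. Esrrb fell 141-fold (adjusted p = 6.3e-06), Klf4 118-fold (adjusted p = 3.8e-05), Tfcp2l1 217-fold (adjusted p = 2.2e-05), Tbx3 864-fold (adjusted p = 0.00021) and Prdm14 at least 791.1-fold. The naive list had a median of -6.74, with 18 of 18 down also over the list alone (adjusted p = 3.6e-12, adjusted p = 0.47 with an estimated correlation). Of 17 early epiblast genes 14 rose and none fell (15 and 0 adjusted over the list alone, median 3.50, adjusted p = 6.9e-07, adjusted p = 0.59 with an estimated correlation). Otx2 rose 19.4-fold (log2 4.28 ± 0.37, adjusted p = 5.1e-05), close to its rise at 35 h, and Dnmt3b rose 19.7-fold (adjusted p = 1.5e-05). Pou3f1 rose 121-fold (adjusted p = 4.5e-05), and Fgf5 was higher by a ratio of 2810 (counting interval 777.5 to 23210).

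Of 16 MEK/ERK genes 10 rose and Etv5 fell, with the same counts over the list alone (median 1.89, adjusted p = 0.0026, adjusted p = 0.59 with an estimated correlation). Dusp6 rose 30.1-fold to 142 ± 31.3 CPM (adjusted p = 4.6e-06) and Egr1, an immediate early factor, rose 61.1-fold. Wnt targets fell in 10 of 14 with Lef1 risen, also over the list alone (median -2.95, adjusted p = 0.0013, adjusted p = 0.47 with an estimated correlation), Axin2 by 24.8-fold to 5.02 ± 0.728 CPM (adjusted p = 6.9e-06) and T by 10.4-fold (adjusted p = 0.0046). LIF/STAT3 targets fell in 8 of 10 although LIF was in the medium, and Junb rose, with the same counts over the list alone (median -2.33, adjusted p = 0.0061, adjusted p = 0.64 with an estimated correlation). Bcl3 fell 27.3-fold and Pim1 6.1-fold. Lefty1 rose 4.95-fold (log2 2.31 ± 0.70, adjusted p = 0.025), a call lost without the CGR8 4-day library (log2 1.71).

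Apical polarity, junction and lumen genes rose in 12 of 20, and Prkci, Prkcz and Ezr fell (13 and 3 adjusted over the list alone, median 0.72, adjusted p = 0.0058, adjusted p = 0.64 with an estimated correlation). Podxl rose 8.61-fold (log2 3.11 ± 0.18, adjusted p = 9.8e-06), Crb3 23.6-fold and Cldn7 46.2-fold, while Cdh1 was not called (log2 0.38, adjusted p = 0.096). Germline genes silenced by DNA methylation fell in 8 of 13, Dazl by 107-fold and Stk31 by 22-fold, and Tdrd1 rose, with the same counts over the list alone (median -2.28, adjusted p = 0.021, adjusted p = 0.64 with an estimated correlation). All 9 2-cell-like genes fell (median -6.01, or -5.32 with bounds, adjusted p = 0.017, adjusted p = 0.71 with an estimated correlation). Cholesterol synthesis genes rose in 9 of 15 with none fallen (9 and 1 adjusted over the list alone, median 0.56, adjusted p = 0.04, adjusted p = 0.64 with an estimated correlation), Lss by 2.93-fold (log2 1.55 ± 0.12). Without the CGR8 L2i library the germline list (0.063) and the 2-cell-like list (0.065) did not pass. The cholesterol list did not pass without R1 L2i (0.067), CGR8 L2i (0.063), R1 4-day (0.12), R1 LIM (0.053) or CGR8 LIM (0.051).

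The other 14 lists had adjusted p between 0.11 and 1, of which the stress response passed without R1 L2i (0.034) or R1 35 h (0.045) and fibroblast markers without CGR8 4-day (0.035). Methylation genes were split, with 3 up, such as Tet3 (4.58-fold), and 5 down, such as Tet2 (68.7-fold) and Uhrf1 (2.33-fold). Trophoblast markers were also split, Krt18 up 74.4-fold and Tfap2c down 113-fold. Median, mean and test direction differed in sign for streak genes (-0.73, -0.24, up) and basement membrane genes (0.13, -0.47, down). In all, 3342 genes were higher and 3618 lower, 44.8% of those tested. The largest rises were in Car4 (at least 1831-fold), Tmem154 (at least 383.6-fold), Trim67 (at least 382.8-fold), Enpp2 (at least 340.3-fold), Spon1 (at least 336.4-fold) and Calcr (at least 261.6-fold). The largest falls besides Prdm14 were in Crxos (at least 1440-fold), Trpm1 (at least 1075-fold), Cdx1 (at least 547.1-fold), Bhmt2 (at least 393.1-fold) and Mobp (at least 331.3-fold). Leaving out single libraries gave 2395 to 3332 higher and 2495 to 3640 lower genes.

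LFAI at 4 days against LIM asked what separates the later LFAI state from the state under MEK inhibition, both without Wnt ligand secretion. Time since L2i differed as well, with 4 (R1) and 6 (CGR8) passages in LIM. All 18 naive factors fell, 8 of 16 MEK/ERK targets rose, and Otx2 was not called. Zfp42 fell 61.2-fold (log2 -5.94 ± 0.18, adjusted p = 1.1e-06), Klf2 102-fold (adjusted p = 7.7e-06) and Nanog 9.16-fold (log2 -3.20 ± 0.33, adjusted p = 0.0003). Dusp6 rose 10.2-fold (log2 3.35 ± 0.21, adjusted p = 2.8e-05). Otx2 (log2 -0.17 ± 0.32, adjusted p = 0.73) and T (0.73, adjusted p = 0.52) were not called.

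All 18 naive factors fell, also over the list alone (median -5.72, adjusted p = 1.2e-13, adjusted p = 0.49 with an estimated correlation), Esrrb 56.8-fold (adjusted p = 2.6e-05), Klf4 48.9-fold (adjusted p = 0.00024), Tfcp2l1 20.3-fold (adjusted p = 0.00049), Tbx3 208-fold (adjusted p = 0.0016) and Prdm14 at least 228.3-fold. Sox2 fell 2.89-fold (adjusted p = 0.00025) and Pou5f1 rose 1.48-fold (adjusted p = 0.028), the latter not called without R1 4-day (log2 0.61), CGR8 4-day (0.51), R1 LIM (0.47) or CGR8 LIM (0.65). Of 17 early epiblast genes 9 rose and Tcf15 and Cdh2 fell (11 and 2 adjusted over the list alone, median 1.12, adjusted p = 0.0077, adjusted p = 0.49 with an estimated correlation). Fgf5 rose 11.2-fold (log2 3.49 ± 0.44, adjusted p = 0.0008), Dnmt3b 2.36-fold (adjusted p = 0.0081) and Pou3f1 4.04-fold (adjusted p = 0.01). Without R1 LIM neither Dnmt3b (log2 1.1) nor Pou3f1 (1.70) was called, nor Pou3f1 without R1 4-day (1.82). Lefty1 rose 6.44-fold (adjusted p = 0.023), not without CGR8 4-day (log2 2.08), R1 LIM (2.25) or CGR8 LIM (3.28).

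Of 16 MEK/ERK genes 8 rose and Fos fell (8 and 2 adjusted over the list alone, median 1.17, adjusted p = 0.0093, adjusted p = 0.49 with an estimated correlation). Neural genes fell in 4 of 6, Pax6 by 39.4-fold and Ncam1, a neural adhesion molecule, by 26.4-fold (log2 -4.72 ± 0.30), and Nes rose 4.22-fold. The neural list passed (5 and 1 over the list alone, median -4.24, or -2.96 with bounds, adjusted p = 0.026, adjusted p = 0.49 with an estimated correlation). Polarity genes rose in 11 of 20, also over the list alone, including Cdh1 (1.99-fold, log2 1.00 ± 0.17, adjusted p = 0.0034), Crb3 (16-fold) and Cldn7 (32.3-fold), and the list passed (median 0.69, adjusted p = 0.0093, adjusted p = 0.49 with an estimated correlation). Podxl was 1 of the 3 that fell, 1.85-fold (log2 -0.89 ± 0.17, adjusted p = 0.0054), not called without CGR8 4-day (-0.79). Basement membrane genes fell in 9 of 16 and none rose, also over the list alone, Nid1 16.4-fold and Fn1 5.2-fold (median -0.82, adjusted p = 0.038, 0.078 with the line as a block, adjusted p = 0.61 with an estimated correlation). Germline genes fell in 9 of 13 with none risen, also over the list alone, Hormad1 48.1-fold (median -2.68, adjusted p = 0.0029, adjusted p = 0.49 with an estimated correlation), and STAT3 targets fell in 6 of 10 with Junb risen (8 and 1 over the list alone, median -2.18, adjusted p = 0.012, adjusted p = 0.49 with an estimated correlation).

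Left-out libraries changed several of these calls. The basement membrane list did not pass without R1 L2i (0.06), CGR8 L2i (0.061), CGR8 4-day (0.17) or R1 LIM (0.18), and the STAT3 list not without CGR8 4-day (0.066). The neural list did not pass without R1 L2i (0.073), CGR8 L2i (0.075), CGR8 4-day (0.11), R1 35 h (0.074), CGR8 35 h (0.063) or R1 LIM (0.061). The other 15 lists had adjusted p between 0.053 and 0.78. Without R1 4-day, BMP targets (0.023), methylation genes (0.049) and trophoblast markers (0.017) passed, as did glycolysis genes without R1 LIM (0.0029), Nodal targets without CGR8 LIM (0.011), and 2-cell-like genes without R1 or CGR8 35 h (0.03 and 0.023). Among their members Axin2 fell 3.34-fold (adjusted p = 0.0011), Notum 56.7-fold (log2 -5.83 ± 0.22, adjusted p = 3.3e-06), Bmp4 13.5-fold and Dnmt3l 58-fold (log2 -5.86 ± 0.32). The 2-cell-like list (median -3.79, or -3.15 with bounds) passed with the line as a block (0.043), and bounds changed the medians of Wnt targets (-0.68 to -0.09) and trophoblast markers (-2.16 to -1.03). Median, mean and test direction differed in sign for streak genes (0.36, -0.26, up) and fibroblast markers (-0.17, 0.46, up).

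In this comparison 1913 genes were higher and 2671 lower. Among the largest rises were those in Macc1 (at least 115.3-fold), Slc22a3 (ratio 1430, counting interval 256.2 to 56520), Pde4b (114-fold), Mal2 (93.7-fold) and Galnt3 (65.4-fold). The largest falls besides Prdm14 were in Cyp26a1, which degrades retinoic acid (at least 102.4-fold), Lrrc31 (at least 83.07-fold), Crxos (at least 82.75-fold), Adgrf5 (at least 72.29-fold) and Six3 (at least 66.9-fold). The higher count became 1097 without R1 4-day, 735 without CGR8 4-day, 961 without R1 LIM and 934 without CGR8 LIM. The lower count became 1358 without CGR8 4-day and 1742 without CGR8 LIM, and with 8 lists called, 5 were called without CGR8 4-day.

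LFAI at 35 h against LIM asked what separates cells early in LFAI from cells under MEK inhibition when both states have early epiblast genes on. The LIM cells had 4 (R1) and 6 (CGR8) passages in LIM, so effects of medium and of time since L2i cannot be told apart. Otx2 (log2 -0.06, adjusted p = 0.94), Dnmt3b (0.25, adjusted p = 0.63), Fgf5 (-0.51, adjusted p = 0.54, called without R1 35 h at -1.55), Zfp42 (-0.10, adjusted p = 0.75), Nanog (-0.29, adjusted p = 0.64) and Esrrb (0.29, adjusted p = 0.6) were not called. Otx2 (log2 0.68 in R1, -0.78 in CGR8), Dnmt3b (0.76 and -0.4) and Fgf5 (0.42 and -1.8) moved in opposite directions in the lines. Their pooled values therefore do not show equal levels in both states. Zfp42, Nanog and Esrrb each moved in the same direction in both lines. Of 16 MEK/ERK targets 5 rose, and of 9 Nodal targets 4 rose and 1 fell. Dusp6 rose 3.93-fold, from 14.0 ± 0.784 to 54.9 ± 4.52 CPM (adjusted p = 0.0024), and Spry4 rose 18.5-fold (log2 4.21 ± 0.43, adjusted p = 0.0022). Lefty1 rose 17.1-fold (log2 4.09 ± 0.75, adjusted p = 0.019), not called without R1 35 h (4.12), CGR8 35 h (4.08), R1 LIM (3.69) or CGR8 LIM (4.69). Podxl fell 2.79-fold (log2 -1.48 ± 0.17, adjusted p = 0.0037), Col4a1 8.13-fold (log2 -3.02 ± 0.29, adjusted p = 0.0017) and Lss 2.23-fold (log2 -1.16 ± 0.12, adjusted p = 0.0024).

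Of the 23 lists 11 passed. MEK/ERK genes rose in 5 of 16 (7 and 1 lower over the list alone, median 0.52, adjusted p = 0.0018, adjusted p = 0.29 with an estimated correlation), and Nodal targets rose in 4 of 9 with Gsc fallen (5 and 1 over the list alone, median 1.14, adjusted p = 0.0036, adjusted p = 0.29 with an estimated correlation). Core factors passed with Dppa2 risen (6 and 1 lower over the list alone, median 0.45, adjusted p = 0.016, adjusted p = 0.22 with an estimated correlation). Cholesterol genes fell in 5 of 15 (12 over the list alone, median -0.49, adjusted p = 3.1e-05, adjusted p = 0.22 with an estimated correlation), and trophoblast markers, Tfap2c down 4.68-fold, in 5 of 10 (7 over the list alone, median -2.37, or -1.96 with bounds, adjusted p = 0.00015, adjusted p = 0.22 with an estimated correlation). Primitive endoderm markers fell in 4 of 10 (7 over the list alone, median -2.24, adjusted p = 0.00056, adjusted p = 0.22 with an estimated correlation), and neural genes, Pax6 among them, in 3 of 6 (4 over the list alone, median -1.37, adjusted p = 0.00093, adjusted p = 0.22 with an estimated correlation). The basement membrane list passed with 4 of 16 fallen, also over the list alone (median -0.43, adjusted p = 0.026, adjusted p = 0.79 with an estimated correlation), and the streak list with Gsc fallen (4 over the list alone, median -2.08, adjusted p = 0.019, adjusted p = 0.22 with an estimated correlation). Col4a1, Lamb1 and Sparc were among the fallen genes of both the basement membrane and the primitive endoderm list. Fibroblast markers fell in 2 of 7 (5 over the list alone, median -1.15, adjusted p = 0.005, adjusted p = 0.22 with an estimated correlation). The 2-cell-like list passed upward without a called gene (median 2.68, adjusted p = 0.01, adjusted p = 0.74 with an estimated correlation). With the line as a block, Zscan4b (0.044) and Zscan4d (0.022) were called higher, as was Tdgf1 of the core list (0.016), and Wnt3 (0.045) and Gata4 (0.03) of the streak list were called lower.

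Several of these lists rested on single libraries. The streak list did not pass without CGR8 35 h (0.072) or R1 LIM (0.13), basement membrane genes not without R1 35 h (0.18) or R1 LIM (0.31), and fibroblast markers (0.092) and 2-cell-like genes (0.25) not without CGR8 35 h. The glycolysis list (0.53) passed downward without R1 LIM (3.9e-05) and upward without CGR8 LIM (0.0071). The other 12 lists had adjusted p between 0.06 and 0.76. STAT3 targets passed without R1 35 h (0.015) or R1 LIM (0.04), naive factors without R1 35 h (0.042), the stress response without CGR8 35 h (0.04), germline genes without R1 LIM (0.0091), and BMP targets without R1 4-day (0.018), CGR8 4-day (0.018) or CGR8 35 h (0.024). Among members, Gsc was not called without R1 35 h (log2 -4.89), CGR8 35 h (-3.96) or R1 LIM (-3.93), Pax6 not without CGR8 35 h (-2.88) or R1 LIM (-2.41), and Dppa2 not without R1 35 h (0.90) or R1 LIM (0.90). The Wnt median was -0.39, or -0.05 with bounds, and formative genes (0.10, -0.05, up), polarity genes (-0.11, -0.08, up) and p53 targets (0.07, -0.13, up) differed in sign between median, mean and test.

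Only 298 genes were higher and 692 lower, the fewest of the 6 comparisons, and with the line as a block 494 were higher. Without the filter they were 746 and 1459, by DESeq2 636 and 1074, and with only the libraries of both groups 188 and 425. The largest rises were in Nlrc4 (31.1-fold, log2 4.96 ± 0.47), Kirrel2 (23.4-fold) and Lefty2 (22-fold), and the largest falls in Lmx1b (ratio 953.9, counting interval 263.7 to 7882), Cyp26a1 (at least 100.9-fold) and Acta2 (at least 95.89-fold). Lefty2 was not called without CGR8 35 h (log2 4.16) or R1 LIM (3.87), Cyp26a1 not without R1 35 h (-10.39), CGR8 35 h (-10.38) or R1 LIM (-8.96), and Acta2 not without R1 35 h (-10.31) or CGR8 35 h (-10.30). Without R1 35 h, CGR8 35 h or R1 LIM, 98, 69 and 64 genes were higher and 185, 146 and 194 lower.

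LFAI at 4 days against 35 h asked which changes come late in LFAI. On the log2 scale the naive factors fell mostly in this interval. In CPM, of the naive panel genes only Zfp42 clearly did so (790 in L2i, 660 at 35 h, 11.6 at 4 days). Esrrb was near even (908, 448 and 6.41). Nanog (1070, 252 and 33.6), Tfcp2l1 (1240, 172 and 5.7), Klf2, Klf4, Tbx3 and Prdm14 lost more CPM before 35 h. Otx2 (log2 -0.10, adjusted p = 0.82) and Pou5f1 (0.13, adjusted p = 0.56) were not called. Otx2 went from 250 to 170 CPM in R1 and from 158 to 209 in CGR8. Zfp42 fell 57.1-fold (log2 -5.83 ± 0.18, adjusted p = 8.7e-07), Klf2 65.9-fold (adjusted p = 6.2e-06) and Nanog 7.51-fold (adjusted p = 0.00027). Fgf5 rose 16-fold (log2 4.00 ± 0.45, adjusted p = 0.0003), Pou3f1 3.93-fold (adjusted p = 0.0086) and Dusp6 2.59-fold (log2 1.37 ± 0.20, adjusted p = 0.00099). Notum, which inactivates Wnt proteins, fell by a log2 fold of -7.23 ± 0.22 (adjusted p = 8.7e-07) and Axin2 fell 4.77-fold (adjusted p = 0.00023).

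Esrrb fell 69.6-fold, Tfcp2l1 30.1-fold (adjusted p = 0.0002), Klf4 40.8-fold (adjusted p = 0.00019), Tbx3 241-fold (adjusted p = 0.0009), Prdm14 at least 148.9-fold and Sox2 3.58-fold (adjusted p = 7.2e-05). Dnmt3b rose 1.98-fold (adjusted p = 0.016, lost without CGR8 4-day, log2 0.90), Cdh1 1.54-fold (adjusted p = 0.02) and Podxl 1.51-fold (adjusted p = 0.024). Cdh1 and Podxl were not called without R1 4-day (log2 0.56 and 0.48), CGR8 4-day (0.66 and 0.67) or CGR8 35 h (0.40 and 0.41). Lefty1 was not called (log2 -1.40 ± 0.67, adjusted p = 0.13), but was without R1 L2i (-1.43) or CGR8 L2i (-1.44).

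All 18 naive factors fell, also over the list alone (median -5.59, adjusted p = 5.2e-13, adjusted p = 0.46 with an estimated correlation), as did all 9 2-cell-like genes (median -6.86, or -5.85 with bounds, adjusted p = 0.0089, adjusted p = 0.68 with an estimated correlation). Core factors fell in 7 of 10, Dppa2 12.1-fold, and Lin28a rose, also over the list alone (median -1.01, adjusted p = 0.024, adjusted p = 0.46 with an estimated correlation). Early epiblast genes rose in 9 of 17, Lin28b 5.25-fold, and Tcf15 fell 8.02-fold, also over the list alone (median 0.99, adjusted p = 0.024, adjusted p = 0.68 with an estimated correlation). STAT3 targets fell in 9 of 10 with Junb risen, also over the list alone (median -2.29, adjusted p = 0.0058, adjusted p = 0.66 with an estimated correlation), and polarity genes rose in 13 of 20 with Prkci and Ezr fallen, also over the list alone (median 0.68, adjusted p = 0.0074, adjusted p = 0.66 with an estimated correlation). Germline genes fell in 5 of 13 with Tdrd1 risen (6 and 1 over the list alone, median -1.84, adjusted p = 0.034, adjusted p = 0.68 with an estimated correlation), a pass lost without R1 L2i (0.055), CGR8 L2i (0.061) or R1 4-day (0.081). Fibroblast markers rose in 2 of 7 (3 over the list alone, median 1.66, adjusted p = 0.034, adjusted p = 0.46 with an estimated correlation), a pass lost without R1 4-day (0.081).

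The other 15 lists had adjusted p between 0.056 and 0.82. Methylation genes passed without CGR8 35 h (0.036), cholesterol genes without CGR8 4-day (0.016) or R1 35 h (0.047), and the stress response without R1 35 h (0.036). Bounds changed the medians of neural genes (-2.29 to -1.16) and Wnt targets (-0.29 to -0.14), and BMP targets (-0.34, 0.30, down) and glycolysis genes (0.13, -0.17, down) differed in sign between median, mean and test. In all, 2750 genes were higher and 2957 lower. The largest rises were in Slc22a3 (at least 446.6-fold), Acta2 (at least 229.2-fold) and Mcoln3 (at least 132.3-fold), and the largest falls besides Prdm14 in Crxos (at least 140.4-fold) and Lrrc31 (at least 109.6-fold). The higher count became 1737 and 1635 without R1 or CGR8 4-day and 1724 and 1440 without R1 or CGR8 35 h. The lower count became 1879 without CGR8 4-day and 1904 without CGR8 35 h.

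A further test asked which genes are highest or lowest in LIM, against both L2i and LFAI at 4 days, calling only genes that passed in both. LFAI at 35 h was not part of that test. Among the genes highest in LIM, Pou4f2, a neuronal homeobox factor, reached 10.5 ± 2.15 CPM (log2 6.54 over L2i and 5.97 over 4 days, adjusted p = 0.013), and Six3, a forebrain and eye factor, was 5.25 log2 units over L2i and at least 66.9-fold over 4 days (adjusted p = 0.03). Its antisense gene Six3os1 was at least 61.74-fold and at least 52.31-fold higher (adjusted p = 0.048), and Cldn2 at least 70.35-fold over L2i (adjusted p = 0.043). Wnt5a (ratio 342.4 over L2i, counting interval 60.99 to 13570, adjusted p = 0.043) and Foxd4 (ratio 253.7, counting interval 45.08 to 10060, adjusted p = 0.03) followed. Lower in LIM than in both were Ctsc, a lysosomal protease (5.86 ± 1.21 CPM against 52.5 ± 4.36 and 48.6 ± 1.88, adjusted p = 0.0029), and Fbln5 (log2 -5.31 and -5.42, adjusted p = 0.014), each also low at 35 h (7.35 ± 2.28 CPM for Ctsc, and 0.13 ± 0.0925 against 0.275 ± 0.0532 in LIM for Fbln5). Also lower in LIM than in L2i and at 4 days were Etv4 (log2 -3.02 and -4.39, adjusted p = 0.03) and Kirrel2 (-2.95 and -3.51, adjusted p = 0.012). Smad7 (log2 -1.99 and -2.19, adjusted p = 0.03) and Pttg1 (-1.56 and -1.43, adjusted p = 0.043) were lower too, and of the panel Podxl came nearest to highest (adjusted p = 0.071).

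In all, 66 genes were highest and 16 lowest in LIM, and with the line as a block 139 and 31. The highest count became 7 without R1 L2i, 9 without CGR8 L2i, 13 without R1 4-day, 9 without CGR8 4-day, 11 without R1 LIM and 28 without CGR8 LIM. The lowest count became 2, 5, 4, 3, 3 and 7 in the same order. Of the named genes only Ctsc was called whichever library was left out. Kirrel2 was not called without R1 L2i (0.067) or R1 LIM (0.075), Pou4f2 not without R1 4-day (0.092), CGR8 4-day (0.12) or R1 LIM (0.071), and Fbln5 not without R1 L2i (0.058), CGR8 4-day (0.091), R1 LIM (0.089) or CGR8 LIM (0.091). Etv4 was lost with any 1 of the L2i and 4-day libraries left out (0.073 to 0.13), and Smad7 with any of those or R1 LIM left out (0.067 to 0.13). Six3 (0.071 to 0.16), Six3os1 (0.13 to 0.25), Foxd4 (0.061 to 0.22), Pttg1 (0.11 to 0.25), Cldn2 (0.056 to 0.21) and Wnt5a (0.054 to 0.19) were lost with any 1 of the L2i, LIM and 4-day libraries left out. Cldn2 was also lost without R1 35 h, and Wnt5a without either 35 h library.

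The time course asked in what order R1 cells leave L2i. It has single libraries, so values are given without tests. Passages in 2i were 5 for day 0, 4 for days 1 to 3 and 3 for day 4 in both media, all at passage 32. Changes from day 0, and from day 3 to day 4, therefore also carry a difference in time in 2i. The LFAI day 1 library lay beside LIM day 1 (SD of log2 ratios 0.153), so by itself it does not place a response in LFAI. Otx2 was up at day 1 in LIM (log2 2.60) and in that library (2.66), and at day 4 in both media (3.39 and 3.37). In LFAI, Dusp6 went from 0.94 at day 1 to 4.00 at day 2, and Dnmt3b stood at 2.99 at day 2 and 4.20 at day 4. Nanog was lower by day 3, at 52.7 CPM against 824 at day 0, and higher again at day 4, at 123 CPM (log2 -2.74). Zfp42 (log2 -4.17), Klf2 (-3.20), Esrrb (-5.38) and Tfcp2l1 (-6.24) were low by day 4, and Fgf5 reached 43.6 CPM from 0 counts on day 0. In LIM at day 4, Nanog stood at 841 CPM (log2 0.03, counting interval -0.01 to 0.07), Zfp42 was higher than on day 0 (log2 0.46, counting interval 0.43 to 0.50), Tfcp2l1 (-2.17) and Axin2 (-4.17) were lower, and Dnmt3b was 0.63.

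**Figure D3:**
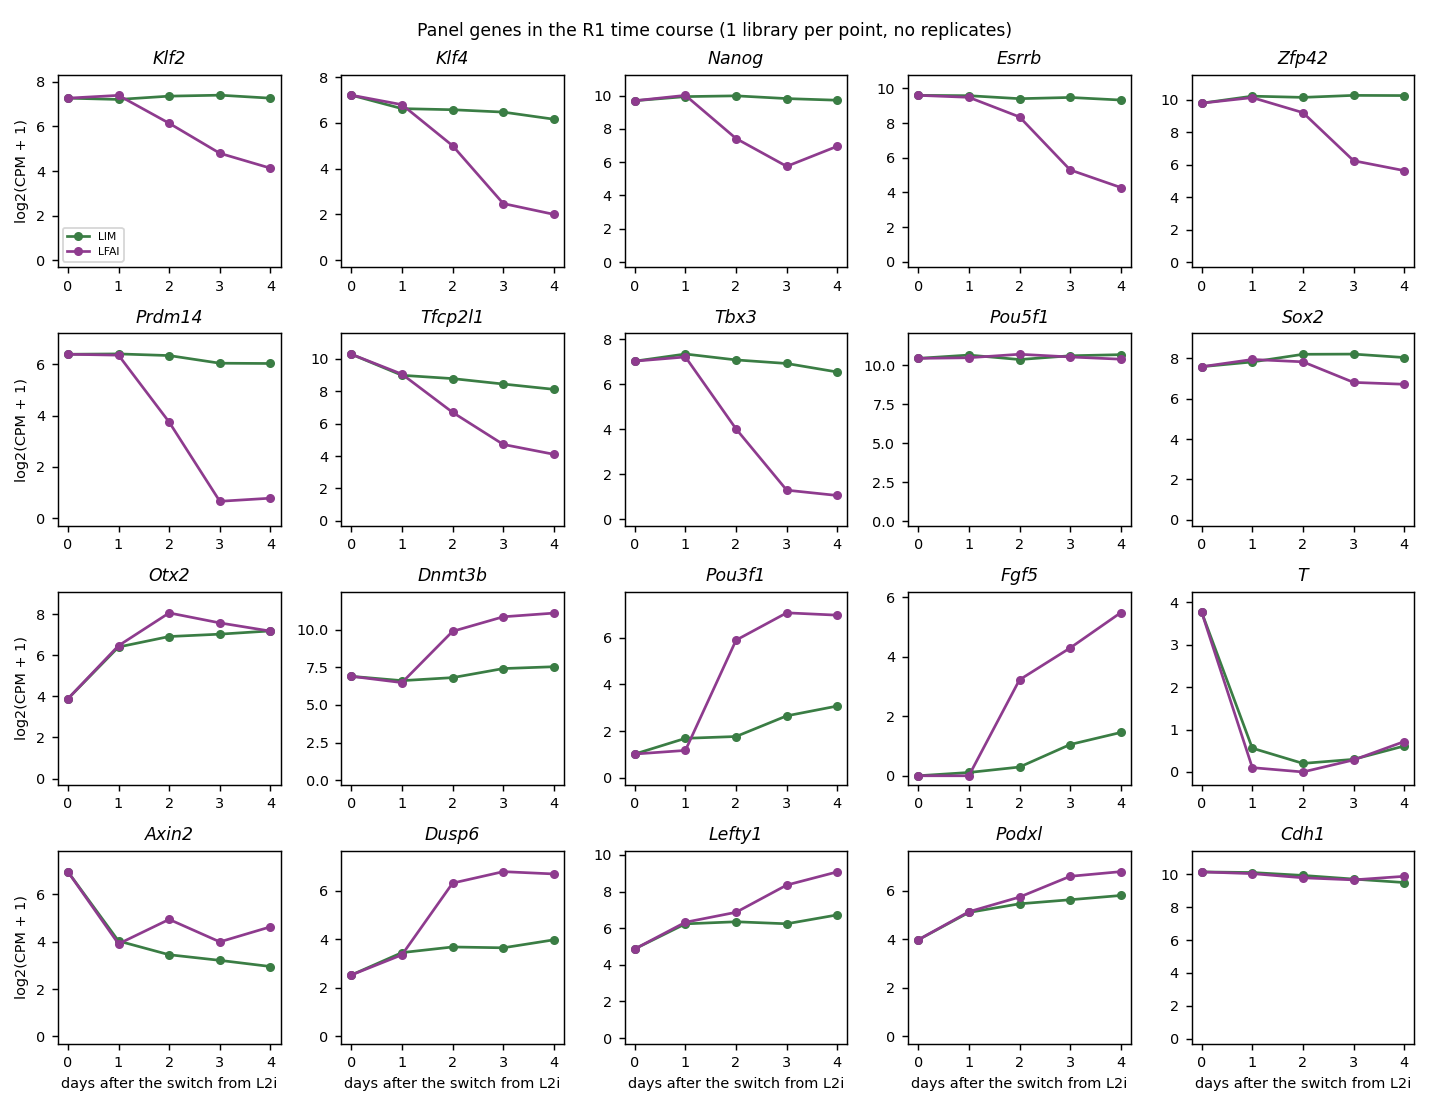
Expression of the panel genes on each day of the time course in LIM and in LFAI (R1, 1 library per point).

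Lists in the time course were placed among 10000 random lists matched for expression. At day 4 of LFAI, the naive list had a median of -3.41 (counting interval -3.69 to -3.22, percentile 0), after 0.14, -1.31 and -3.30 on days 1 to 3. Early epiblast genes stood at 0.00 on day 1, 2.74 on day 2 and 2.86 on day 4 (percentile 100), MEK/ERK genes at -0.10, 1.36 and 1.51 (percentile 100), and Nodal targets at 0.24, 1.09 and 0.99 (percentile 99.99). Wnt targets were already at -1.82 in LIM on day 1 and at -1.58 in the library labelled LFAI day 1. That library lay beside LIM day 1, so day 1 values given for LFAI, here and below, may not be those of LFAI cells. In LIM at day 4, naive genes stood at -0.13 (counting interval -0.16 to -0.03, percentile 3.17), early epiblast genes at 1.37 (percentile 100), Wnt targets at -1.09 (percentile 0), neural genes at 1.83 (percentile 100) and MEK/ERK genes at 0.00 (percentile 49.02). Without the low-count filter the neural median was 0.84 in LIM and 1.37 in LFAI, where it was 0.55 with the filter, so the order of the media turned. The Wnt median in LFAI, -2.58 at day 4, was -1.71 without it. Cholesterol genes were at 0.70 in LIM and 0.83 in LFAI (percentile 100 in each), STAT3 targets at -0.87 and -0.81. Germline genes (2.12) and 2-cell-like genes (2.33) were high at day 4 of LFAI, where both lists fell in the set with both lines.

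**Figure D4:**
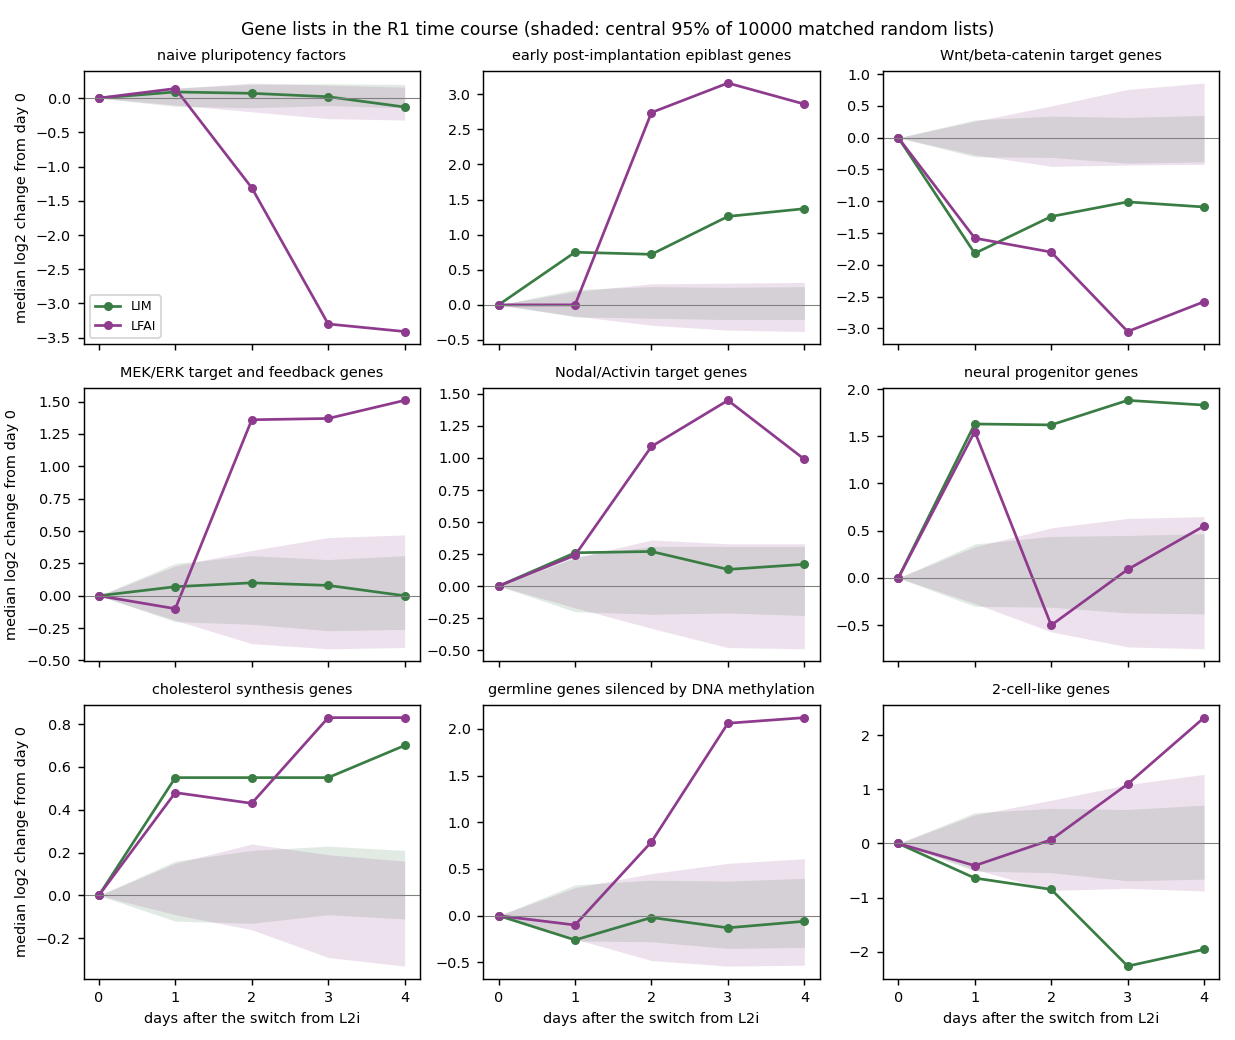
Median log2 change from day 0 of 9 gene lists in the time course. Shading marks the central 95% of random lists of the same size and expression.

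The genes with the largest steady change over the days were led in LIM by Lrtm2 (28.8-fold), Myrf (28.7-fold), Crabp2, a retinoic acid binding protein (26.5-fold), Lmx1b (25.4-fold) and Fgfr2 (19.5-fold) upward. Downward they were Trpm1 (159-fold), Nkx1-2 (122-fold), Gpx2 (55-fold), Axin2 (17.9-fold) and Ctsc (16.5-fold). In LFAI they were Kif1a (279-fold), Mmp25 (202-fold), Has2 (log2 7.55 on 1 count, counting interval 6.67 to 14.46, with 0.0731 CPM on day 0 and 0.0733 on day 1), Fgf15 (113-fold) and Rims4 (68.3-fold) upward, and Crxos (log2 -8.08), Trpm1 (-7.57), Ntn1 (107-fold), Lrrc31 (81.9-fold) and Tfcp2l1 (75.7-fold) downward. Genes changing at least 2-fold from day 0 rose in number from 1538 on day 1 to 2415 on day 4 in LIM and from 1337 to 4654 in LFAI, of 15682. LFAI and LIM differed at least 2-fold in 602 genes on day 1 and in 2964 on day 2.

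Changes across genes were compared between the experiments in 4 relations, with genes not independent replicates. Over 14905 genes, LFAI day 4 correlated with the 4-day change at 0.76 (slope 0.48), LIM day 4 with the LIM change at 0.55 (slope 0.34), and LFAI day 2 with the 35 h change at 0.73. LFAI day 1 correlated with the 35 h change at 0.31. The LIM relation sets 4 days in LIM against 4 (R1) and 6 (CGR8) passages in LIM. Among genes over 10 CPM the first 3 were 0.83, 0.64 and 0.82.

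Library measures bear on single genes in these comparisons. RNA of ribosomal type made up 2.71% of gene counts in R1 L2i, 1.66% in R1 35 h and 2.71% in LIM day 1, and at most 0.65% elsewhere. Genes of chromosome 8 were higher in R1 than in CGR8 by a median log2 of 0.36 in L2i, 0.34 at 35 h and 0.25 in LIM, against 0.03 at 4 days, over 386 genes. Of the panel, Klf2, Zfp42 and Cdh1 lie on that chromosome, and of other named genes Acta1, Ccdc194, Col4a1, Junb, Pou4f2 and Trim67. In LIM against L2i, 86 of its 794 tested genes were higher and 43 lower, 16.2% against 19.2% of other genes. At 4 days against LIM, where only LIM had the higher level in R1, 45 were higher and 144 lower, at 4 days against L2i 134 and 185, and at 4 days against 35 h 110 and 139. At 35 h they were 49 and 48 against L2i, and 7 and 31 against LIM. Without the R1 L2i and R1 35 h libraries together, 923 genes were higher and 581 lower in LIM than in L2i, and 200 and 136 at 35 h against L2i.

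**Figure D5:**
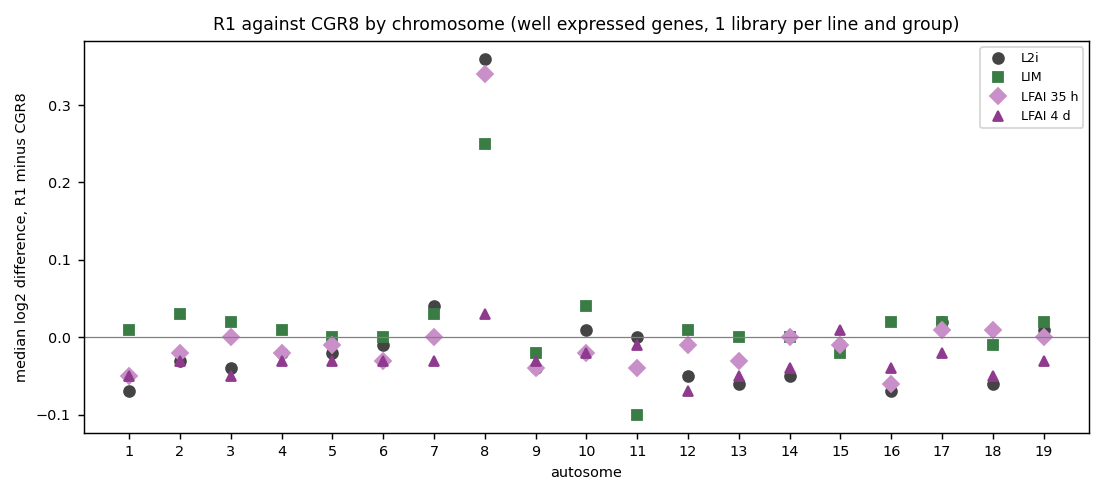
Median log2 difference between R1 and CGR8 per autosome in the 4 groups of the set with both lines.

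In GRCm38 with GENCODE M21 names, Nanog lies on chromosome 6 at 122707489 to 122714633, Zfp42 on chromosome 8 at 43295063 to 43306980 and Otx2 on chromosome 14 at 48657677 to 48673819. Podxl lies on chromosome 6 at 31519488 to 31563981, Dusp6 on chromosome 10 at 99263231 to 99267489 and Axin2 on chromosome 11 at 108920349 to 108950783.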

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

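All 9 tests of explanations in this part were chosen after seeing the results.

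In the time course, the LFAI day 1 library stood beside LIM day 1, with an SD of log2 ratios of 0.153 between them among well expressed genes and 602 genes 2-fold apart. A wrong label, with cells kept in LIM, could give this, and the slope of the day 1 difference on that of day 2 was 2.7e-05 (SE 0.0085, 957 genes), against 0.89 and 0.81 on days 3 and 4. A response to FGF2 and Activin A that starts after day 1 could give it too, and the MEK/ERK median of LFAI over LIM on day 1 was -0.06. Low depth was argued against, since that library had 1.02 times the median depth of the others. Open is which of the first pair holds, because PD325901 carried over from L2i, a slow response and a wrong label predict the same values, and hours before day 1 are not in the data.

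Genes of chromosome 8 were higher in R1 than in CGR8 in L2i, at 35 h and in LIM (0.36, 0.34 and 0.25), but not after 4 days in LFAI (0.03). Extra copies of the chromosome in some R1 cells could give this, as the smallest difference over 3 parts of the chromosome and these 3 groups was 0.24. An effect of 4 days in LFAI was argued against for CGR8, where the chromosome changed by 0.01 against other autosomes, though CGR8 lacks the higher level. In the R1 time course (passage 32), its median deviation from the mean of all libraries was 0.12 on day 0, against -0.01 for other autosomes. On day 4 of LFAI it was -0.06 against -0.13, still higher but by less, and in the R1 4-day library -0.15 against 0.02. Ordinary spread was argued against, as the largest difference of any other autosome was 0.1. The R1 library of 4 days came from passage 26 and the other R1 libraries from passages 30 to 32. Open is whether copies were gained, since DNA was not measured.

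RNA without a poly(A) tail was high in R1 L2i, R1 35 h and LIM day 1, where the smallest median log2 ratio of Rmrp, Rn7sk and Rpph1 over the other libraries was 2.7. That value measures the pattern and so cannot tell whether RNA without a tail was left over in library preparation. The medium was argued against, as the 5 ribosomal-type genes had a ratio of at most 0.21 in the CGR8 libraries of the same groups, against 2.23 and 1.51 in R1, and the other 3 genes had 0.56 in both, against 3.91 and 3.06. Few RNA molecules behind R1 L2i may add to it, as only 18256 genes were detected there at equal depth, against 19002 in the next lowest library of that set. Open are the cause and how far it moves calls, since leaving out both R1 libraries also lowers the number of libraries, to 200 and 136 called genes at 35 h against L2i.

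Some lists had medians of opposite sign in R1 and CGR8, and in each case the difference was not tested. In LIM against L2i these were Nodal targets (-1.1 in R1, 0.42 in CGR8), germline genes (-0.21 and 0.46) and p53 targets (0.44 and -0.28), and the difference was not tested. In LFAI at 4 days against L2i they were basement membrane genes (0.48 and -0.22) and trophoblast markers (-0.28 and 0.22), and the difference was not tested. In LFAI at 4 days against LIM they were glycolysis genes (0.50 and -0.40) and fibroblast markers (0.32 and -0.79), and the difference was not tested. In LFAI at 35 h against LIM they were early epiblast genes (0.68 and -0.60), germline genes (0.35 and -1.01), glycolysis genes (0.43 and -0.89) and the integrated stress response (0.53 and -0.24), and the difference was not tested. In LFAI at 4 days against 35 h they were basement membrane genes (0.51 and -0.51) and the integrated stress response (-0.27 and 1.02), and the difference was not tested.

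The time course and the set with both lines moved some lists in opposite directions. Day 4 of LFAI against the 4-day change in R1 and CGR8 gave 0.55, -1.28 and -1.83 for neural genes, 0.37, -0.64 and -0.74 for DNA methylation machinery, 2.12, -2.01 and -1.47 for germline genes, and 2.33, -2.64 and -5.50 for 2-cell-like genes, and the difference was not tested. For LIM the durations were unlike, 4 days in the time course against 4 (R1) and 6 (CGR8) passages in the other set. Day 4 of LIM against the LIM change gave -1.04, 1.26 and 0.62 for BMP targets, -0.63, 1.12 and 1.80 for trophoblast markers, and -0.62, 1.35 and 1.30 for fibroblast markers, and the difference was not tested. Without the low-count filter that time course median of fibroblast markers was 0.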

How the results depend on the processing

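Of the alternatives in this part, the pair that left out both R1 libraries or chromosome 8 was chosen after seeing the results.

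Over all pairs of a named gene and a setting, the side of the threshold was the same in 8303, a call was lost in 491 and gained in 227. For genes highest or lowest in LIM it was the same in 74 and lost in 58. Over pairs of a list and a setting it was the same in 1488, lost in 84, gained in 83 and reversed in 1, glycolysis at 35 h against LIM without CGR8 LIM (adjusted p = 0.0071, against 0.53 with all libraries and 3.9e-05 downward without R1 LIM). Of counts (by a tolerance of 1.5 times) and of list medians and correlations (within their counting or confidence interval), 408 values stayed and 88 moved. Of time course gene values 229 stayed and 3 moved, all 3 with a prior count of 5, and the cause was not tested.

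Leaving out single libraries gave 934 to 1690 higher and 505 to 1131 lower genes in LIM against L2i, 507 to 1132 and 369 to 1040 at 35 h against L2i, and 735 to 1810 and 1358 to 2650 at 4 days against LIM. At 35 h against LIM the ranges were 64 to 319 and 146 to 693, at 4 days against 35 h 1440 to 2668 and 1879 to 3090, and for genes highest and lowest in LIM 7 to 57 and 2 to 14. Lists called were 6 to 12 in LIM against L2i and 5 to 11 at 4 days against LIM. The cause was not tested.

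A log2 fold threshold of 1 left 676 lower genes in LIM against L2i, 2208 higher at 4 days against L2i, 930 at 4 days against LIM, 184 at 35 h against LIM and 1732 at 4 days against 35 h. The 35 h against LIM counts were 746 and 1459 without the filter, 636 and 1074 by DESeq2, and 188 and 425 with only its groups, and 494 were higher with the line as a block. Genes highest and lowest in LIM were 362 and 80 without the filter and 139 and 31 with the block. With an estimated correlation 0 lists were called in LIM against L2i, 0 at 35 h against L2i, 0 at 4 days against L2i, 0 at 4 days against LIM, 0 at 35 h against LIM and 0 at 4 days against 35 h. By fry, which asks whether a set moves at all in 1 direction and not against other genes, 9 were called in LIM against L2i and 15 at 4 days against L2i. The cause was not tested.

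Without R1 L2i and R1 35 h, higher and lower genes were 923 and 581 in LIM against L2i, 200 and 136 at 35 h against L2i, and 93 and 170 at 35 h against LIM. Higher genes were 2217 at 4 days against L2i and 1771 at 4 days against 35 h, and 11 and 2 genes were highest and lowest in LIM. Without chromosome 8, which holds 794 of the 15525 tested genes, no count moved by 1.5 times. Leaving out so few genes could hardly move a count that far, so this says little about the difference between lines. In the time course without the filter, day 4 medians became 0.84 in LIM and 1.37 in LFAI for neural genes, -1.71 for Wnt targets in LFAI and 0 for fibroblast markers in LIM. Over 10 CPM the correlations became 0.83, 0.64 and 0.82 for LFAI day 4, LIM day 4 and LFAI day 2. The cause was not tested.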

Other observations

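No tests were made for this part, and its genes and values were picked after the values were seen. CPM here are scaled over all 17 libraries together, so they differ somewhat from those of the 8 libraries alone.

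In LIM, Ldha, which makes lactate, stood at 420 CPM in R1 and 1820 in CGR8, the glycolytic enzyme Aldoa at 740 and 2380, and the hypoxia target Bnip3 at 12.4 and 167. R1 cells in LIM in the time course lay between these for Ldha (643 to 760), Aldoa (1300 to 1480) and Bnip3 (23.5 to 49.9). Pdk1, a kinase that limits pyruvate oxidation, was at 302 (R1) and 276 CPM (CGR8) after 35 h in LFAI, against 37.5 and 73.4 in L2i, and reached 401 CPM on day 2 of LFAI in the time course.

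After 4 days in LFAI, Krt8 stood at 211 CPM in R1 and 52.2 in CGR8, Krt18 at 161 and 69.8, and Sfn, a 14-3-3 protein of epithelia, at 453 and 99, while day 4 of the time course had 14, 23.1 and 15.4. Dnmt3l was at 167 CPM on day 4 of the time course and at 11.1 and 10.8 in R1 and CGR8 after 4 days. Ddx4, a germ cell helicase, was at 17.3, 31.1 and 41 CPM on days 2 to 4 of LFAI in the time course.

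Xist was at 12.2, 64.3 and 36.8 CPM on days 2 to 4 of LFAI in the time course, 0.213 on day 0, and 0 and 0.201 after 4 days in the other set.

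Hprt was at 0.205 to 0.668 CPM in the CGR8 libraries and at 84 to 168 in R1, and Ftl1 at 3.96 to 8.52 and 113 to 179, so both genes separate the lines.

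Zscan4c was at 23.8 and Zscan4d at 48.4 CPM on day 4 of LFAI in the time course, and Zscan4c was 0.195 and 0 in R1 and CGR8 after 4 days.

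Dnmt3b was at 179 CPM on day 4 of LIM in the time course, and at 833 and 982 in the R1 and CGR8 LIM libraries, which had been in LIM for 4 and 6 passages.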
